A study of Rattus norvegicus with 29 samples.

How the data were processed

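The series holds 29 Affymetrix rat genome U34 arrays (the A array), 1 for each sample, from hippocampal CA1 tissue of male Fischer rats. Groups were taken from the sample titles, as 9 young (4 months), 10 mid-aged (14 months) and 10 aged (24 months) samples.

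The authors deposited 1 file per array with a signal for each of 8799 probe sets and a detection call of present, marginal or absent, per the file headers. The column names are those of a Microarray Suite 5 type output, and the software version is not given in the sources used here. Each array's signals had been scaled by the authors to nearly the same mean without the lowest and highest 2%, as the deposited values show. The file of 1 young array also held a column of another young array, and that 1 column was not used. A deposited value table of the whole series gives an intensity for each probe set, with values from -39359 to 70317, and between 18.6% and 23.8% of each column lies below 0. Each of its 29 columns followed its own array's signals best by rank (lowest rank correlation 0.851), on an unlogged scale with no centring by gene and the same direction; how it was computed is not given in the sources used here. It served as an alternative.

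The 59 control probe sets were left out. Each array was multiplied so that its trimmed mean over the other 8740 probe sets matched the average over arrays (factors from 0.999 to 1.00). Since 5 values were exactly 0, signals were then floored at the median of all values called absent, 160.8, and log2 was taken. Probe sets called present on at least 9 of 29 arrays were kept (3861). Gene names came from the platform annotation, which gives 7006 probe sets 1 gene, 308 several and 1426 none; 0 symbols needed an update through the RefSeq table of assembly GRCr8. No genome build is given in the sources used here, and no coordinates are printed. For gene lists and named genes each gene was represented by its kept probe set with the highest mean. A fold is on the scale of floored signals. Where a gene was absent on every young array, its fold may rest in part on the floor. Gfap and Gapdh, which were fixed by name, have no kept probe set with a single gene name here.

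The 3 ages were fitted together with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with contrasts for each pair of ages, an F test, and the mid-aged mean against the middle of young and aged. P-values are two-sided and adjusted by Benjamini-Hochberg with a threshold of 0.05. Of the 24 gene lists fixed in advance, 22 had at least 5 measured genes and were tested with limma's camera (inter-gene correlation 0.01), beside camera with an estimated correlation and fry; the lists of complement and of choroid plexus, with 4 measured genes each, were not tested. A second adjustment over all lists and the 3 comparisons ended none of the calls. Measures of RNA quality were compared with exact permutation tests over all 92378 or 184756 groupings, with Python 3, numpy, pandas and scipy; figures were drawn with matplotlib.

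Named genes follow a rule fixed before the data were examined. They are the 12 largest rises and the 12 largest falls aged vs young among genes past the threshold (all 9 falls that passed on the gene's brightest probe set), the 6 largest in each direction for the other pairs of ages, up to 4 members with the smallest p of each described list, and 15 genes fixed by name.

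The steps were tested on simulated data. With 3861 probe sets, 29 arrays and the spread of these data, aged vs young recovered 33.1% of changes of 1.25-fold, 78.2% of changes of 1.5-fold and 97.9% of changes of 2-fold, with 25 of 18300 unchanged probe sets called over 5 runs. For mid-aged vs young, with steps of the square root of those folds, recovery was 0.597%, 15.5% and 58.8%. The straight-line test recovered 43.6% of changes of 1.25-fold and 85.1% of changes of 1.5-fold in the mid-aged group alone. A list shifted by 0.1 on the log2 scale was called in 14 of 20 runs, with 0 of 420 unshifted lists called, and a list shifted by 0.2 in 20 of 20, with 1 of 420; these simulations hold no correlation between genes.

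Alternatives covered the scaling (none, quantile, median), the deposited intensity table, the filter, the floor, an intensity trend, array weights, the replicate number as a block, the Gapdh ratio as a covariate, unlogged values, fits of 2 groups, leaving out each array, and other list tests. Added after seeing the data were the column-name style as a term, fits within each style, leaving out the 6 arrays least like the rest, and hexokinase as control transcript.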

Results

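RNA from the CA1 field of the hippocampus of male Fischer rats was measured on 29 single-colour Affymetrix rat genome U34 arrays (the A array). The arrays fall into 9 from young rats (4 months), 10 from mid-aged rats (14 months) and 10 from aged rats (24 months). All rats had been trained on 2 tasks, which the labels call SWM and OMT, and tissue was taken 24 h after a 7-day sequence. The labels number the samples within each age but do not say that each array holds RNA of 1 rat, which was assumed here, and young 1 is not among the samples. The n and SD therefore count arrays, and p-values measure the spread between these samples. Each array gave 1 signal for each of 8799 probe sets, of which 59 were controls. Between 35.6% and 46.5% of the other 8740 probe sets were called present on an array. The 3861 probe sets called present on at least 9 of the 29 arrays were tested. Of these, 3217 carried 1 gene name, for 2407 genes. The number of arrays limits the precision of every value.

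The first comparison asked how gene expression in CA1 of aged rats differed from that of young rats. The lists of antigen presentation, microglia and myelin genes lay higher in aged rats relative to the other genes, with 5 of 11, 4 of 12 and 2 of 16 genes past the threshold. Ctss counts in both the antigen presentation and the microglia list. Activity-regulated transcripts were lower as a list, with 2 of 26 genes past the threshold by their brightest probe sets. Less bright probe sets of Egr1 and Homer1 also fell past it. The call of the list was lost with an estimated correlation (adjusted p = 0.0888 with an estimated correlation). Past the threshold were 64 probe sets, 46 of them higher and 18 lower in aged rats (limma, Benjamini-Hochberg adjusted). By any of their probe sets they stand for 29 named genes that rose and 14 that fell, and 14 of the probe sets carry no single gene name. The median fold was 1.58 among the rises and 0.673 among the falls, and 7 of the 64 changed by more than 2-fold. At an unadjusted p under 0.05 there were 548 probe sets, against 193 expected by chance. The array columns carry 2 styles of name, and the shorter one marks 5 young, 4 mid-aged and 0 aged arrays. The styles also lay apart within an age. On the third principal component of the arrays, 8.44% of the variance, young arrays averaged 0.33 in the shorter and -0.04 in the longer style. Mid-aged arrays averaged 0.02 and -0.14 in that order. Whether the style marks a processing batch is not given in the sources used here. With the style as a term in the fit 55 probe sets passed aged vs young, only 37 of them among the 64. Among the arrays of the longer style alone, 10 of them aged and 4 young, 16 passed.

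At the floor used here the largest rise was that of Cd74, the invariant chain that accompanies class II molecules. Cd74 was called present on 0 of 9 young, 3 of 10 mid-aged and 8 of 10 aged arrays, and was 3.10-fold higher in aged than in young rats on the scale of floored signals (adjusted p = 2.95e-04). Being absent on every young array, its young level lies near the floor, so the size and rank of that fold depend on the floor. RT1-Da, a class II alpha chain, rose from 9.44 ± 0.30 (SD, n = 9) to 10.57 ± 0.41 (SD, n = 10) on the log2 scale, a fold of 2.18 (adjusted p = 3.05e-04). RT1-Db1, a class II beta chain, was present on 1 of 9 young, 3 of 10 mid-aged and 9 of 10 aged arrays. It rose 1.65-fold, and 4 of 10 aged arrays lay above all young ones. Under the other settings its log2 change ran from 0.14 to 1.16. The brightest probe set of Efemp1, an extracellular matrix protein, was present on 0 of 9 young and 7 of 10 aged arrays. It was 2.12-fold higher on the scale of floored signals (adjusted p = 7.67e-04). A second Efemp1 probe set, present on 5 of 9 young and 7 of 10 aged arrays, differed by 0.04 on the log2 scale (adjusted p = 0.899).

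Both kept beta-globin probe sets rose, that named Hbb by 1.30 ± 0.22 (SE) and that named Hbb-b1 by 0.93 ± 0.13 (SE) on the log2 scale. For each, all 10 aged arrays lay above every young array. Whether they read separate transcripts was not tested. Ptgds, which makes prostaglandin D2, rose 1.90-fold, from 12.20 ± 0.20 (SD, n = 9) to 13.12 ± 0.26 (SD, n = 10) on the log2 scale (adjusted p = 8.54e-06). Rhoa, a small GTPase, rose 1.84-fold, Cryab, a small heat shock protein, 1.64-fold and Lamp2, a lysosomal membrane protein, 1.56-fold. A second Cryab probe set stood at +0.37 (adjusted p = 0.226), and of the 2 other Lamp2 probe sets 1 rose by 0.61 and 1 stood at +0.13 (adjusted p = 0.659). Fcgr2b, an Fc receptor, rose 1.72-fold and C1qb, a chain of complement C1q, 1.54-fold. For both Fcgr2b and C1qb all 10 aged arrays lay above every young array. With the name style in the fit, Rhoa no longer passed, though its log2 change lay between 0.74 and 0.96 under all settings run for it.

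**Figure D1:**
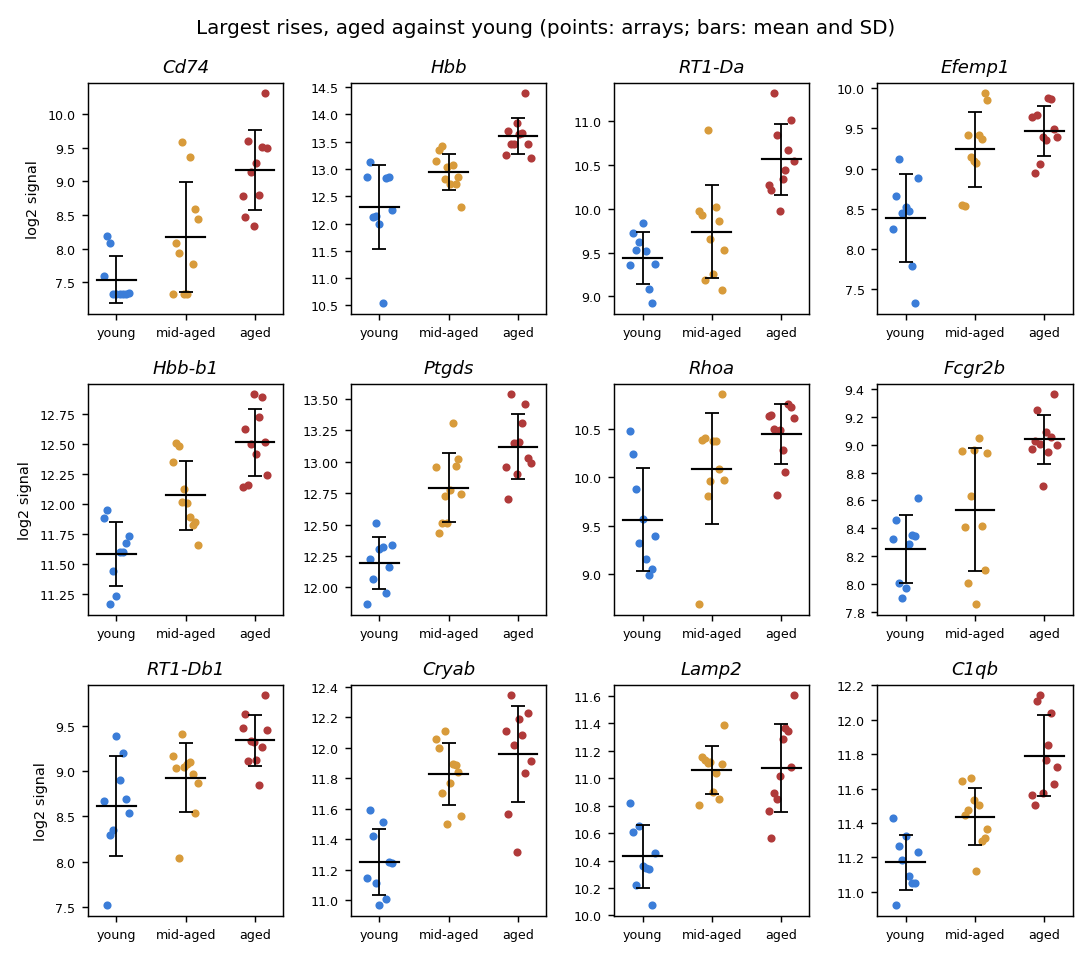
Log2 signal of the 12 genes with the largest rises, aged against young, with a point for each array and the mean and SD of each age (9 young, 10 mid-aged and 10 aged arrays). For Cd74, Hbb, RT1-Da, Hbb-b1, Ptgds, Fcgr2b and C1qb all 10 aged arrays lie above every young one.

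Among the falls, Egr2, an activity-induced transcription factor, fell by 0.94 ± 0.20 (SE) on the log2 scale (adjusted p = 0.00543), and 9 of 10 aged arrays lay below the young median. Its aged mean, 7.84, lay near the floor, and under the other settings its change ran from -1.43 to -0.29. Plagl1, an imprinted zinc finger gene, fell by 0.79 ± 0.17 (SE), and Ndn, another imprinted gene, fell by 0.57 ± 0.13 (SE). Lpl, lipoprotein lipase, fell by 0.59 ± 0.11 (SE), and its 2 other probe sets fell by 0.74 and 0.46. Arc, an activity-regulated synaptic gene, fell from 12.93 ± 0.26 (SD, n = 9) to 12.38 ± 0.40 (SD, n = 10) on the log2 scale (adjusted p = 0.0282), lower than the young median on 10 of 10 aged arrays. Vof16 fell by 0.67, Pus3 by 0.62, Bud13 by 0.46 and Dnaja1, a co-chaperone, by 0.36, while a second Dnaja1 probe set stood at -0.06 (adjusted p = 0.884). Pus3 was present on only 5 of 9 young and 3 of 10 aged arrays. Of these 9 genes, Plagl1, Vof16, Pus3, Ndn, Arc, Bud13 and Dnaja1 did not pass with the name style in the fit. Over all other settings their log2 changes nearest to 0 were -0.58, -0.50, -0.01, -0.37, -0.34, -0.31 and -0.27 in that order.

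Of these 12 rises and of the 9 falls by a gene's brightest probe set, 6 passed among the arrays of the longer name style alone. Cd74, Egr2 and Pus3 did not pass with a floor at the 75th percentile of the absent values, and Bud13, Efemp1, Lamp2, Pus3, RT1-Db1 and Vof16 did not pass in the deposited series table. Without the 6 arrays least like the rest, RT1-Db1, Arc, Bud13 and Vof16 did not pass. Arc, Rhoa, RT1-Db1 and Vof16 did not pass without a filter on dim probe sets, and Pus3 did not with a floor at the 25th percentile. Cd74, Efemp1, RT1-Db1, Plagl1, Vof16 and Pus3 were not tested when presence on at least 20 arrays was required.

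**Figure D2:**
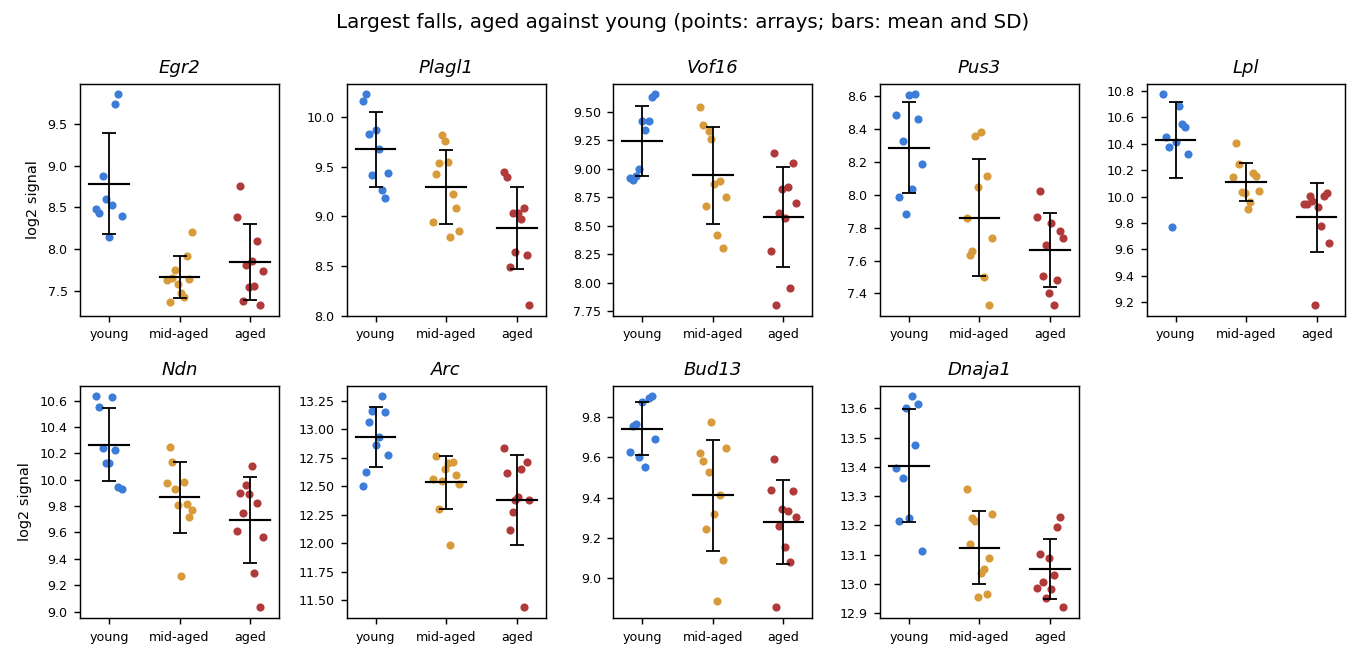
Log2 signal of the 9 genes that fell by their brightest probe set, aged against young, drawn as for the rises. Egr2 stood at 8.78 ± 0.61 (SD, n = 9) in young and 7.84 ± 0.45 (SD, n = 10) in aged rats.

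Gene lists were fixed before the data were examined, and 7 of the 22 with at least 5 measured genes passed aged vs young (camera), 6 higher and 1 lower. The series keywords name synaptic plasticity, myelin, inflammation and memory, so lists on those themes are not independent evidence of what moved. The lists also overlap, with 33 genes in more than 1, so their calls are not independent of each other. Ctss counts in the antigen presentation, microglia and lysosome lists. Of 100 splits of the arrays, the ages themselves among them, 7 gave as many lists, so the number of lists does not stand out from chance. The antigen presentation list lay 0.46 above the other genes on the log2 scale (adjusted p = 1.37e-07, and adjusted p = 0.0157 with an estimated correlation). The mean change of the list was 0.44, but its median was 0.18. Of its 11 measured genes, 5 rose, and 5 also when adjusted over the list alone. They were Cd74, RT1-Da, RT1-Db1, B2m, the class I light chain (+0.40 ± 0.10, SE), and Ctss, a protease of microglia and antigen-presenting cells (+0.39 ± 0.08, SE). B2m did not pass with the name style in the fit, in the longer style alone or without the 6 arrays least like the rest, and Ctss did not pass in the longer style alone. Of the 12 measured microglia and macrophage markers, 4 rose (adjusted over the list alone, 7 rose and 1 fell), and 11 changes were positive. The 4 were C1qb, Fcgr2b, Ctss and Aif1, the last by 0.48 ± 0.12 (SE). Aif1 did not pass without a filter on dim probe sets, with the name style in the fit or in the longer style alone. Its log2 change lay between 0.45 and 0.70 under the other settings, and a second Aif1 probe set stood at +0.33 (adjusted p = 0.0844). The microglia list lay 0.30 above the other genes (adjusted p = 1.37e-07, and adjusted p = 0.00552 with an estimated correlation).

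The 16 measured myelin and oligodendrocyte markers lay 0.23 above the other genes (adjusted p = 4.96e-07, and adjusted p = 0.0332 with an estimated correlation). Mag, a myelin membrane protein, rose by 0.61 ± 0.10 (SE) and Pmp22 by 0.36 ± 0.08 (SE), and the other 14 did not pass. Neither passed in the deposited series table or in the longer name style alone, and Pmp22 did not pass with the style in the fit. Adjusted over the list alone, 7 rose. A second Pmp22 probe set stood at -0.17 (adjusted p = 0.608). Lpar1 stood at +0.51 (adjusted p = 0.0907) and Mobp, a myelin basic protein of oligodendrocytes, at +0.29 (adjusted p = 0.0983). Mbp, the main myelin basic protein, stood at +0.17 ± 0.12 (SE, adjusted p = 0.559). For the antigen presentation, microglia, myelin and immediate early lists no other split of the 100 gave as large a shift. The largest other shift, whatever its sign, was 0.346, 0.228, 0.213 and 0.2181 in that order. For the immediate early list, with a shift of -0.2189, another split thus came very close.

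The 26 measured immediate early and activity-regulated genes lay 0.22 below the other genes, a shift of -0.22 (adjusted p = 2.57e-05). With an estimated correlation the call was lost (adjusted p = 0.0888), and it was lost without the 6 arrays least like the rest, where the shift was -0.12 (adjusted p = 0.0773). By each gene's brightest probe set, only Egr2 and Arc fell when adjusted over all probe sets tested, and 9 members fell when adjusted over the list alone. Vgf, a secreted neuropeptide precursor, stood at -0.43 ± 0.12 (SE, adjusted p = 0.0692) and Nptx2, a neuronal pentraxin, at -0.36 ± 0.10 (SE, adjusted p = 0.0730). Egr1 stood at -0.23 (adjusted p = 0.440) on its brightest probe set, while another Egr1 probe set fell by 0.41 (adjusted p = 0.0141). Homer1, a postsynaptic scaffold, stood at -0.14 (adjusted p = 0.628) on its brightest probe set, while another fell by 0.68 (adjusted p = 7.17e-04) and the remaining 3 stood between -0.03 and 0.08. The brightest probe set of Bdnf, a neurotrophin, differed by 0.0036 (adjusted p = 0.994).

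The lysosome list lay 0.12 above the other genes (22 genes, adjusted p = 3.20e-04). With an estimated correlation its adjusted p was 0.0888. Lamp2 and Ctss rose, and also when adjusted over the list alone, while Grn stood at +0.21 (adjusted p = 0.173) and Ctsl at +0.20 (adjusted p = 0.185). The astrocyte list lay 0.17 above the other genes (26 genes, adjusted p = 0.00160, and adjusted p = 0.0888 with an estimated correlation). None of its genes passed, with either adjustment. Its members with the smallest p were Id3 at +0.48 (adjusted p = 0.0983), Vim at +0.40 (adjusted p = 0.140), Fabp5 at -0.17 (adjusted p = 0.206) and S100b at +0.23 (adjusted p = 0.259). A second Id3 probe set stood at +0.07 (adjusted p = 0.862). Apoe, a lipid carrier made by astrocytes, stood at +0.15 (adjusted p = 0.632). The ribosomal protein list lay 0.13 above the other genes (38 genes, adjusted p = 5.00e-06). Its call was lost with an estimated correlation (adjusted p = 0.262) and without the 6 arrays least like the rest (0.05, adjusted p = 0.0773), and 7 of the 100 splits, the ages themselves among them, gave as large a shift. Of its genes 34 changes were positive and 0 passed, or 4 when adjusted over the list alone, with Rpl26 at +0.48 (adjusted p = 0.0822), Rps10 at +0.27 (adjusted p = 0.0911), Rpl36 at +0.21 (adjusted p = 0.102) and Rpl21 at +0.31 (adjusted p = 0.110). A second Rpl26 probe set stood at +0.19, and the other Rpl21 probe sets at +0.12, -0.20 and -0.13, none of them past the threshold.

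Markers of neurons as a whole did not shift detectably against the other genes (29 genes, 0.02, adjusted p = 0.921), and Snap25, a synaptic vesicle fusion protein, stood at -0.09 ± 0.16 (SE, adjusted p = 0.842). The 17 markers of inhibitory interneurons stood at -0.07 (adjusted p = 0.229), with Gad1, which makes GABA, at -0.08 (adjusted p = 0.775) and Sst at -0.01 (adjusted p = 0.984). A second Sst probe set stood at -0.27 (adjusted p = 0.0736). The list of glutamate receptors and postsynaptic signalling stood at 0.08 (adjusted p = 0.0719) and that of the respiratory chain and ATP synthase at -0.05 (adjusted p = 0.123). Without the 6 arrays least like the rest both passed, at 0.19 (adjusted p = 1.59e-04) and -0.11 (adjusted p = 0.00336). The vascular and blood cell list stood at 0.20 with a median of -0.09 over 7 genes (adjusted p = 0.138). Its 2 genes that rose were Hbb and Hbb-b1, by the beta-globin probe sets above. That list passed with the name style in the fit (0.31, adjusted p = 0.0166) and among the arrays of the longer style (0.28, adjusted p = 0.0190). The 10 other lists, among them calcium handling, cytokines, chaperones, oxidative stress defence and cholesterol synthesis, had adjusted p-values between 0.152 and 0.916.

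With the name style in the fit the 7 lists kept their calls, with shifts of 0.45 for antigen presentation, 0.33 for microglia, 0.18 for myelin, 0.17 for astrocytes, 0.12 for lysosome, 0.10 for ribosomal proteins and -0.19 for immediate early genes. Among the arrays of the longer style the shifts were 0.44, 0.34, 0.16, 0.16, 0.12, 0.08 and -0.17 in that order, and the astrocyte list did not pass (adjusted p = 0.127).

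**Figure D3:**
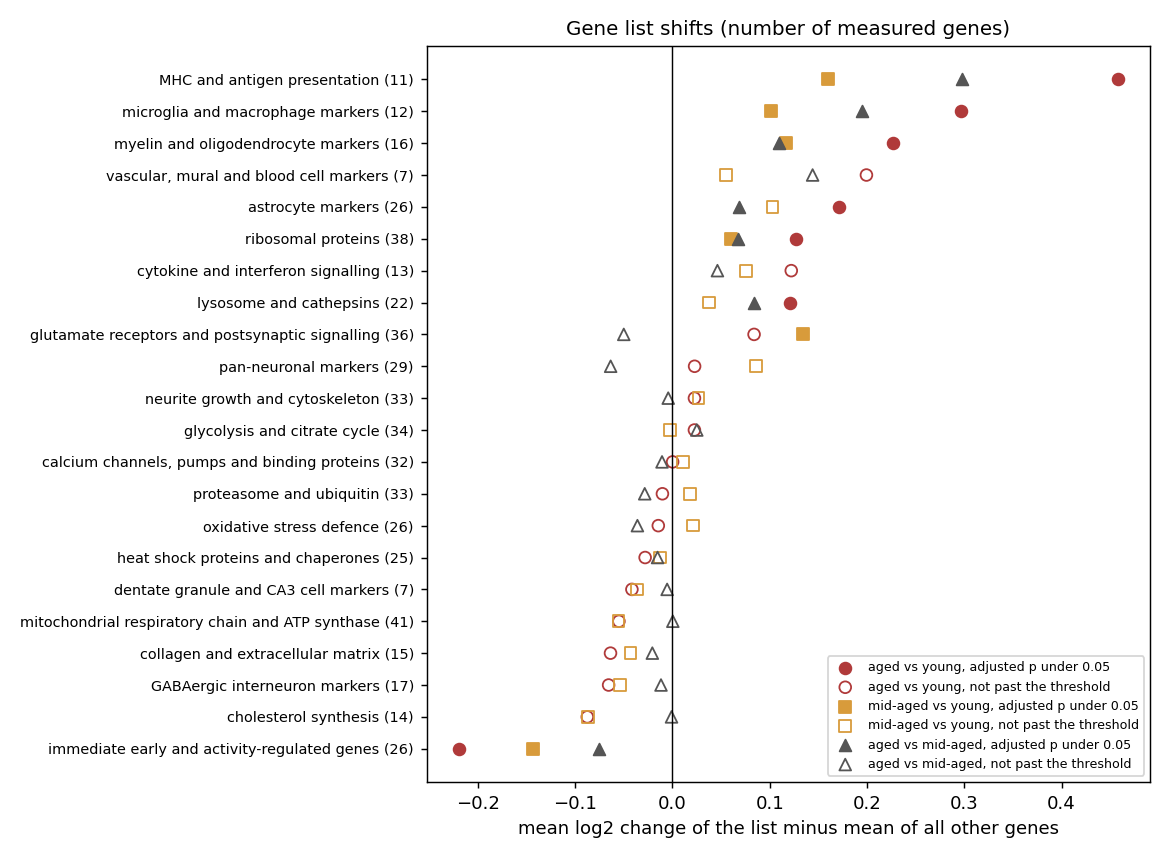
Shift of each gene list, the mean log2 change of its genes minus that of all other genes, for the 3 comparisons of ages (filled symbols, adjusted p under 0.05). The antigen presentation list lies farthest right, at 0.46 aged vs young, and the immediate early list farthest left, at -0.22.

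The mid-aged rats show how much of this was present at 14 months. Ptgds, Cryab, Lamp2 and Efemp1 were already higher in mid-aged than in young rats, by 0.60 ± 0.11, 0.58 ± 0.12, 0.63 ± 0.11 and 0.85 ± 0.19 (SE) on the log2 scale. Qdpr, which regenerates a cofactor of monoamine synthesis, was higher by 0.45 ± 0.09 (SE, adjusted p = 0.00854). Egr2 fell by 1.12 ± 0.20 (SE, adjusted p = 0.00548), Slc15a4, a peptide and histidine transporter, fell by 0.42 ± 0.09 (SE), and Npy, an interneuron peptide, fell by 0.39 ± 0.09 (SE, adjusted p = 0.0370). The mid-aged mean of Egr2, 7.66, lay near the floor, so the size of its fall may depend on the floor. In all 16 probe sets passed (limma), 10 higher and 6 lower. Among the arrays of the longer name style, 6 mid-aged and 4 young, 0 passed, and 23 passed among those of the shorter style, 4 mid-aged and 5 young, only 2 of them among the 16. At an unadjusted p under 0.05 there were 431.

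Mid-aged vs young, 6 lists passed, and none with an estimated correlation, where the adjusted p-values were 0.354 or more. The myelin list lay 0.12 (adjusted p = 0.0106), the glutamate receptor list 0.13 (adjusted p = 0.0106), the ribosomal protein list 0.06 (adjusted p = 0.0229), the antigen presentation list 0.16 (adjusted p = 0.0307) and the microglia list 0.10 (adjusted p = 0.0329) above the other genes. The immediate early list stood at -0.14 (adjusted p = 0.0191). Among the arrays of either name style alone none of the 6 lists passed, with adjusted p-values of at least 0.167 in the longer and 0.137 in the shorter style. Without the 6 arrays least like the rest only the myelin (0.13, adjusted p = 0.0193) and glutamate receptor (0.18, adjusted p = 3.50e-04) lists passed. Of the glutamate receptor list the members with the smallest p aged vs young were Arc, Grik1 at +0.38 (adjusted p = 0.0953), Grin2c at +0.40 (adjusted p = 0.0989) and Ppp3ca at +0.41 (adjusted p = 0.268).

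Between mid-aged and aged rats 2 probe sets passed, 1 higher and 1 lower in aged rats, and neither carries a single gene name here. At an unadjusted p under 0.05 there were 200, against 193 expected by chance (limma). None of the immune transcripts named above passed singly, with RT1-Da at +0.83, Cd74 at +1.00, Fcgr2b at +0.50, C1qb at +0.35, Aif1 at +0.21 and B2m at +0.14 on the log2 scale. The microglia list lay 0.19 above the other genes (adjusted p = 2.97e-06, and adjusted p = 0.0127 with an estimated correlation) and the antigen presentation list 0.30 (adjusted p = 2.97e-06, and adjusted p = 0.0377 with an estimated correlation). The lists of myelin (0.11), lysosome (0.08), ribosomal proteins (0.07), astrocytes (0.07) and immediate early genes (-0.08) also passed, and each was lost with an estimated correlation, where the adjusted p-values were 0.264, 0.264, 0.598, 0.354 and 0.492. With the name style in the fit the lists of myelin (adjusted p = 0.0846), ribosomal proteins (adjusted p = 0.134), astrocytes (adjusted p = 0.173) and immediate early genes (adjusted p = 0.211) did not pass. Without the 6 arrays least like the rest these 4 and the lysosome list (0.05, adjusted p = 0.176) did not pass, and the immediate early list stood at 0.01 (adjusted p = 0.904), with its sign turned.

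Across the 3 ages 51 probe sets differed (limma F test). Of the 64 probe sets called aged vs young, 45 had a mid-aged mean nearer to the aged than to the young mean. These were chosen by their difference between aged and young arrays, and no value expected without a change was computed for that number. A test of the mid-aged mean against the middle of young and aged called 0 probe sets (limma), with 202 at an unadjusted p under 0.05 and a smallest adjusted p of 0.135. No single probe set was thus shown to depart from a straight line in age.

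Measures of RNA quality did not differ detectably between ages. The Gapdh 3'/5' log2 ratio was -0.05 ± 0.25 (SD, n = 9) in young, -0.14 ± 0.22 (SD, n = 10) in mid-aged and 0.05 ± 0.36 (SD, n = 10) in aged rats, and the aged minus young difference was 0.10 (exact permutation test, two-sided, p = 0.495, adjusted p = 0.857). For beta-actin that difference was -0.19 (exact permutation test, p = 0.383, adjusted p = 0.857). The share of probe sets called present was 39.4% ± 1.40 (SD, n = 9) in young and 41.6% ± 2.53 (SD, n = 10) in aged rats (exact permutation test, p = 0.0391, adjusted p = 0.390 over the 12 tests). Across the 29 arrays the first principal component, 25.2% of the variance, followed the Gapdh ratio (Pearson r = 0.82, permutation p = 1e-05, the smallest these permutations can give; Spearman rho = 0.76, permutation p = 3e-05). Without the 2 arrays farthest from the median ratio r was 0.71. The arrays aged 3, aged 4, aged 8, mid-aged 1, mid-aged 8 and young 4 had median correlations with the others of at most 0.957, against 0.963 or more for the rest. Without these 6 arrays 131 probe sets passed aged vs young, 54 of them among the 64. With weights for array quality 326 passed, with all 64 among them.

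**Figure D4:**
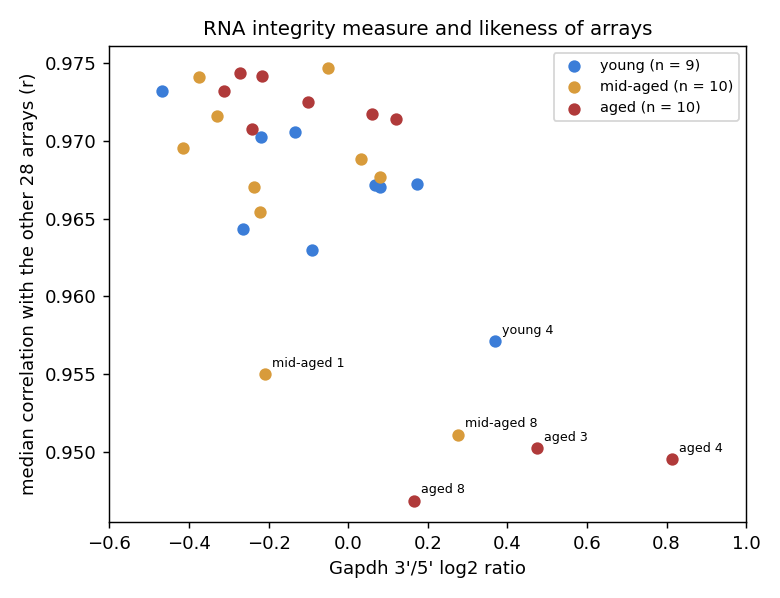
Median correlation of each array's log2 values with those of the other 28 arrays, against the array's Gapdh 3'/5' log2 ratio. The 6 named arrays lie at 0.957 or below, and aged 4 has the highest ratio, 0.81.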

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

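The tests of blood and of white matter below, the fits with the column-name style and those without the 6 arrays least like the rest were chosen only after results had been seen. Of 168 groups of samples scanned for a sample far from the others of its age, 12 held one, and chance gives about 1 in 20, or 8.4. The value given for each is the sample's gap to its nearest neighbour as a share of the range of its group.

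Of the 12, 3 lie in aged 8: Hbb was high (0.470; 14.39 against a mean of 13.52 for the others, log2), Apoe was high (0.543) and Arc was low (0.486; 11.44 against 12.49). In aged 3, Vim (0.519) and Sst (0.532) were high. Rpl26 was low in aged 2 (0.582), Rpl36 high in aged 4 (0.504) and Lpl low in aged 5 (0.553). Lpl was also low in young 5 (0.549) and Hbb in young 7 (0.563; 10.55 against 12.52). RT1-Da was high in mid-aged 4 (0.480) and Rhoa low in mid-aged 1 (0.513). Aged 3, aged 4, aged 8 and mid-aged 1 are among the 6 arrays least like the rest.

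The beta-globin rise could come from more blood left in aged tissue, in which case alpha-globin should rise as much. The alpha-globin change minus that of the brightest beta-globin probe set was -1.22 ± 0.32 (SE), but the alpha-globin probe set was present on 1 array, so this cannot tell. With the column-name style in the fit the mean beta-globin change was 1.19, against 1.11 without it, which speaks against the style as its source. A change within CA1 cells remains possible.

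The myelin list could be higher because aged pieces held more white matter, in which case its members should rise by like amounts. They ranged from -0.09 to 0.61, a wider spread than their errors give (permutation p = 5.00e-04), which speaks against a simple shared factor but not against a mixture of cells with unequal markers. With the Gapdh ratio in the fit the list shift was 0.22, so RNA quality by that measure does not account for it. That ratio differed by only 0.10 between aged and young arrays, so the fit is a weak test of RNA quality.

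The immediate early list kept a shift of -0.19 (-0.189) with the Gapdh ratio in the fit and of -0.19 (-0.189) with the column-name style in the fit, which speaks against either as the whole source. For RNA quality the Gapdh fit is again a weak test, since aged and young arrays differed little in that ratio. Without the 6 arrays least like the rest the list's shift was -0.12 and its call was lost (adjusted p = 0.0773). A lower response to training and a lower resting level in aged rats cannot be told apart here, since all rats were trained.

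Each count was set against 100 splits of the arrays into groups of the same sizes, the ages themselves among them. A count as large was seen in 1 split for the 64 probe sets aged vs young (highest other 38), in 1 for the 16 mid-aged vs young (highest other 1), in 3 for the 2 aged vs mid-aged (highest other 15) and in 1 for the 51 across the ages (highest other 38). It was seen in 7 for the 7 lists aged vs young (highest other 9), so chance is not excluded for that number, in 2 for the 6 lists mid-aged vs young (highest other 7) and in 4 for the 7 lists aged vs mid-aged (highest other 7). For the straight line, with 0 called, every split must give a count as large, so that comparison can tell nothing. The highest other count was 93. Those splits mix arrays of all 3 ages, so age differences and other structure among the arrays cannot be told apart as its source.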

How the results depend on the processing

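Aged vs young, the direction of every called list stayed the same under each alternative run for lists, which leave out fits of 2 groups, and that of every named gene past the threshold under the settings run for single genes, which leave out unlogged values, fits of 2 groups and leaving out 1 array. The 64 probe sets called aged vs young became 94 with the series value table (44 shared), 326 with array weights and 98 with the Gapdh ratio in the fit. They became 131 without the 6 arrays least like the rest and 16 among arrays of the longer column-name style. The other settings gave 55 to 80, and with the style in the fit only 37 of 55 were shared. The 16 mid-aged vs young became 8 with the series value table, 87 with array weights, 7 unlogged, 64 without the 6 arrays and 0 in the longer style. The 2 aged vs mid-aged became 0 with the series value table, without a filter, with the Gapdh ratio, without the 6 arrays and with only the 2 groups in the fit. The 0 off a straight line became 1 unlogged and 1 with the style in the fit. The 51 across the ages became 210 with array weights, 87 without the 6 arrays and 10 in the longer style. The cause was not tested, save that the longer style leaves 20 arrays, 4 of them young.

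The 7 lists became 11 with the series value table and 3 with an estimated correlation. Without the 6 arrays 7 passed, but the immediate early and ribosomal protein lists were lost and 2 others gained, and fry kept 6 of the 7, without the ribosomal protein list (adjusted p = 0.0765), and gained those of GABAergic interneurons and cholesterol synthesis, both down (adjusted p = 0.0167 and 0.00724). Of the 21 rises and falls named aged vs young, 13 kept their call with the style in the fit and 6 in the longer style. C1qb, Hbb, Hbb-b1, Ptgds and RT1-Da kept theirs under all 15 settings run for them.

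Leaving out 1 array at a time gave 52 to 84 probe sets aged vs young, 8 to 22 mid-aged vs young, 0 to 4 aged vs mid-aged, 39 to 56 across the ages, 0 to 0 off a straight line and 7 to 9 lists, and each of the 7 lists kept its call. The mid-aged vs young count moved by more than 1.5 times without young 7, young 8, young 9, mid-aged 4 or mid-aged 7. The aged vs mid-aged count did so without aged 2, aged 3, aged 4, aged 9, mid-aged 2, mid-aged 3, mid-aged 4, mid-aged 5, mid-aged 6 or mid-aged 10.

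With the replicate number as a block, 77, 13, 2, 0 and 53 probe sets and 8 lists passed, and of the 21 named genes Vof16 did not. Of 28 pairs of arrays with the same number, 13 correlated above 0.1 and 6 best with their own number. No numbers expected by chance were computed, so these counts neither show nor exclude a pairing. The labels give no pairing. Dim signals limit the analysis, since only 3861 of 8740 probe sets were called present often enough to be tested.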

Other observations

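Apod, a lipid carrier, stood at 0.49 ± 0.14 (SE, adjusted p = 0.0830) and Col1a1 and Col3a1, fibrillar collagens, stood at -0.44 and -0.62 aged vs young (adjusted p = 0.0721 and 0.0761). A second probe set of Col1a1 fell by 0.57 (adjusted p = 0.0101). Mgst1, a glutathione transferase, stood at 0.51 (adjusted p = 0.0698) and was present on 1 of 9 young, 8 of 10 mid-aged and 9 of 10 aged arrays. A second probe set of Cyp51, a cholesterol synthesis enzyme, fell by 0.34 (adjusted p = 0.0409), while its brightest stood at -0.31 (adjusted p = 0.332). The remaining Cyp51 probe set stood at -0.01 (adjusted p = 0.993).

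Plagl1 and Ndn are both imprinted, and a hypothesis formed on seeing them was that imprinted genes fall together with age. The 10 other measured imprinted genes had a shift of -0.12 ± 0.11 (SE over genes, camera p = 0.357), with 7 changes negative and 0 called. The hypothesis was not borne out for this list, though a smaller shared fall is not excluded. Which of these genes are imprinted in CA1 was not tested, so the list cannot decide the question there.

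A hypothesis for Ptgds and Efemp1 was more meninges in aged tissue pieces. The 14 other meningeal markers had a shift of -0.10 ± 0.09 (SE over genes, camera p = 0.173) with 0 called, against a mean of 1.00 for Ptgds and Efemp1.

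Another hypothesis, written after results had been seen, was that arrays differ more from each other in older rats. The mean distance was 0.328 ± 0.046 (SD) in young and 0.357 ± 0.086 (SD) in aged rats (exact permutation p = 0.402), which cannot tell.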
